A study of Sorghum bicolor with 4 samples.

How the data were processed

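Total RNA from the middle internode of the stem was measured in the sweet sorghum variety SSV84 (Sorghum bicolor), grown in an open field. Per the labels' protocols, RNA was isolated by a modified Trizol method and libraries were made with a stranded total RNA kit. The samples used here were 2 libraries at booting, 1 at the milky stage and 1 at physiological maturity. Per the submitters' processing notes, the tools were cutadapt 1.8.1, Bowtie2 2.2.9, HISAT2 2.0.5 and Cuffdiff. The role of each tool and the version of Cuffdiff are not given in the sources used here. The genome build is not given in the sources used here either, so coordinates are those of the deposited table.

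The deposited values are FPKM (fragments scaled by transcript length and by the number of mapped fragments), per the file headers, with 1 value for each stage made by the authors. No column was labelled as a single library, and how many libraries entered each stage value, or how they were combined, is not given in the sources used here. The values are therefore printed as the authors' value for the stage, with no SD and no n. The comparisons have no replicate check, and no p-value was computed.

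The table held 34458 rows, of which 31423 carried a single gene ID, 1262 carried several IDs merged into 1 row, and 1773 carried none (unannotated transcribed loci). The files do not pair the IDs with gene names. Of the 34129 distinct gene IDs, 0 were found as written in the RefSeq gene table for the assembly Sorghum_bicolor_NCBIv3, so no gene is named or described by function. Conversion between ID formats was not tried, so the 0 does not show that the RefSeq table lacks these genes. Before the data were examined, 25 gene lists had been fixed by description, among them R2R3 MYB factors, cellulose, xylan and lignin synthesis, sucrose metabolism and markers of other tissues. With no descriptions to search, 0 of the 25 lists found a row, and none is reported.

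The design fixed before the data were examined was a limma fit on log2(FPKM + 1) over all 4 libraries. With 1 value per stage this could not be fitted, and the rule of size fixed beside it was used alone. A row entered with at least 1 FPKM in at least 1 stage, which kept 18505 rows. It was counted as having risen or fallen when log2(FPKM + 1) differed by at least 1 between stages, and the words rose and fell are used for such rows. The added 1 understates the change of rows with low values. Stage patterns crossed the direction of both steps, and the counts were set beside their mean over all orders of the 3 values within each row.

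The fixed rule for named genes needed limma calls and descriptions. In its place, the 2 genes with the largest rise and the 2 with the largest fall were named in each comparison, among rows with a single ID and above 0 in both stages. That reduction was made after the data were seen. The alternatives tried were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, rescaling each stage by the median of ratios, quantile normalization and a log2 difference of at least 2. The code was tested on simulated data for maturity vs booting with 200 changed rows among 18505. The simulation had counting error at an assumed depth and no spread between plants or libraries. The changed rows were drawn only from those with a mean of at least 5 FPKM, so recovery at lower values was not tested. Of the changed rows, the rule recovered 0% at 1.5-fold, 99.5% at 3-fold and 100% at 8-fold. These shares follow mostly from the threshold itself and give no rate of false calls. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

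Sequencing depth is not stated in the table. For positional counts, 1 expressed row was kept per locus on the 10 chromosomes, and calls were shuffled 1000 times over positions.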

Results

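Gene expression in the middle internode of field-grown sweet sorghum SSV84 was compared across 3 stages of development, booting, the milky stage and physiological maturity. The title of the series places the samples in a study of R2R3 MYB factors in sorghum. Each stage had 1 FPKM value per row, made by the authors. All differences below therefore have no replicate check, and the spread between plants or libraries is not known from these values.

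Of the 34458 rows, 18505 reached 1 FPKM in at least 1 stage and 7333 were at 0 in all stages. Rows at 1 FPKM or more numbered 16871 at booting, 17103 at the milky stage and 17461 at maturity, and 15847 reached that level in all stages. Detection at 1 FPKM in a single stage was most frequent at maturity, with 701 rows, against 399 for booting and 322 for the milky stage. Among rows at 1 FPKM or more, the median was 12.8 FPKM at booting, 12.6 at the milky stage and 12.9 at maturity. The 10 highest rows held 8.03% of the summed FPKM at booting, 9.16% at the milky stage and 6.83% at maturity. The row with the highest mean lay on chromosome 1 from 11339408 to 11340551, with 11251 FPKM at booting, 11621 at the milky stage and 8557 at maturity.

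From booting to the milky stage, Sobic.009G116700 (chromosome 9, 45915614 to 45916682) rose from 0.106 to 42.3 FPKM, a log2 difference of 5.29. Sobic.002G141800 (chromosome 2, 23093097 to 23093995) rose from 0.284 to 42.6 FPKM (5.09) and stood at 44.3 FPKM at maturity. The largest fall was that of Sobic.005G046700 (chromosome 5, 4444213 to 4445054), from 327 to 5.49 FPKM (−5.66). Sobic.009G231600 (chromosome 9, 57151986 to 57161564) fell from 65.8 to 1.31 FPKM (−4.86) and was at 0.235 FPKM at maturity. In all, 894 rows rose and 1092 fell, and 138 rose and 170 fell by a log2 difference of at least 2. With a pseudocount of 0.1 the excess of falls turned, with 1638 rising and 1544 falling. The median log2 difference over all expressed rows was −0.01, and 72.6% of rows stayed within 1.5-fold in FPKM + 1. Rows with low values can be among these with a larger ratio of FPKM. Rows with a mean of 100 FPKM or more fell more often than they rose, 112 against 50 of 1265.

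The comparison of maturity with booting spanned the whole series and gave the most changed rows, 1499 that rose and 1146 that fell. Sobic.009G116700 rose further to 155 FPKM at maturity, a log2 difference of 7.14 from booting. Sobic.001G425600 (chromosome 1, 70540574 to 70541384) rose from 0.0480 FPKM at booting through 2.41 at the milky stage to 93.1 at maturity (6.49). Sobic.005G046700 fell to 0.549 FPKM (−7.72), and Sobic.008G162600 (chromosome 8, 59632341 to 59636299) fell from 478 through 98.2 to 5.31 FPKM (−6.25). Changes of at least 2 on the log2 scale numbered 343 upward and 224 downward. Direction differed with expression level. Among 7597 rows with a mean of 1 to 10 FPKM, 841 rose and 484 fell, whereas among 1265 rows at 100 FPKM or more 45 rose and 140 fell. Of those 1265 rows, 40 rose and 39 fell from the milky stage to maturity. The excess of falls among abundant rows was thus seen only against booting, where 1416 rows reached 100 FPKM, against 1195 at the milky stage and 1231 at maturity. Whether it lies in the scaling of the booting values was not tested. The excess of rises over all rows from booting to maturity turned under other settings, with 1226 rising and 1279 falling after quantile normalization, and 754 rising and 775 falling among rows with a mean of at least 5 FPKM.

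From the milky stage to maturity, 1040 rows rose and 672 fell. The excess of rises was smaller under other scalings, with 924 rising and 766 falling after rescaling by the median of ratios, and 912 rising and 842 falling after quantile normalization. Sobic.004G263100 (chromosome 4, 60812267 to 60813930) rose from 0.587 to 68.8 FPKM (5.46), after 0.268 FPKM at booting. Sobic.002G109500 (chromosome 2, 13337492 to 13338174) went from 59.1 FPKM at booting to 2.57 at the milky stage and 149 at maturity, a log2 difference of 5.40 for the later step. Sobic.001G519700 (chromosome 1, 78556200 to 78558856) fell from 214 to 0.973 FPKM (−6.77), and Sobic.002G072200 (chromosome 2, 7347191 to 7348612) fell from 73.8 to 0.261 FPKM (−5.89). Both had been lower at booting than at the milky stage, at 69.7 and 27.9 FPKM. Changes of at least 2 on the log2 scale numbered 215 upward and 126 downward. By chromosome, rises were most frequent on chromosome 8, with 96 of 1022 rows (9.39%), and least frequent on chromosome 7, with 50 of 1251 rows.

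**Figure D1:**
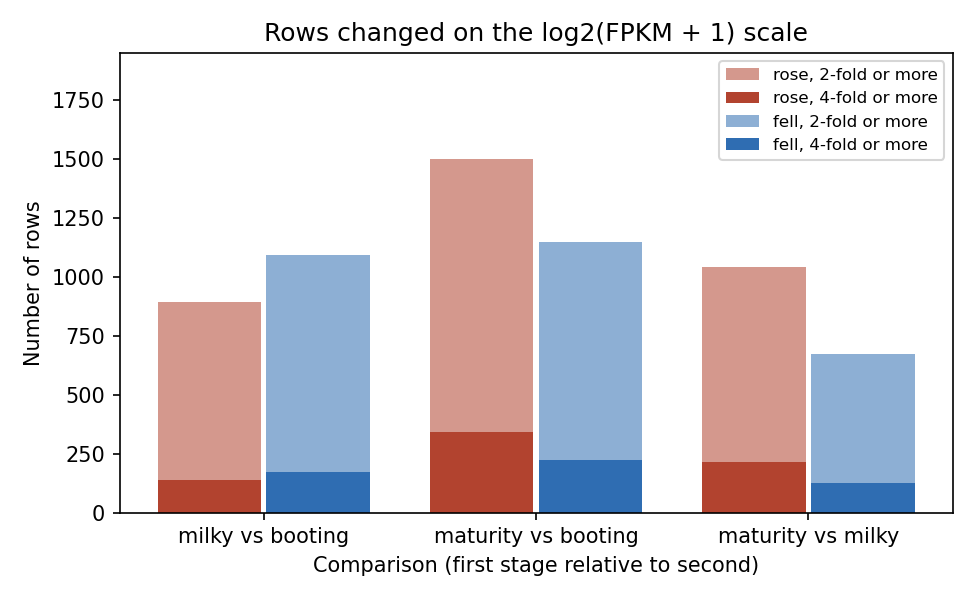
Number of expressed rows (vertical axis) that rose or fell in each comparison, with light bars for a log2(FPKM + 1) difference of at least 1 and dark bars for at least 2. Rises outnumber falls in maturity vs booting (1499 and 1146) and maturity vs milky (1040 and 672), and falls outnumber rises in milky vs booting (1092 and 894), at the settings used for the main counts.

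**Figure D2:**
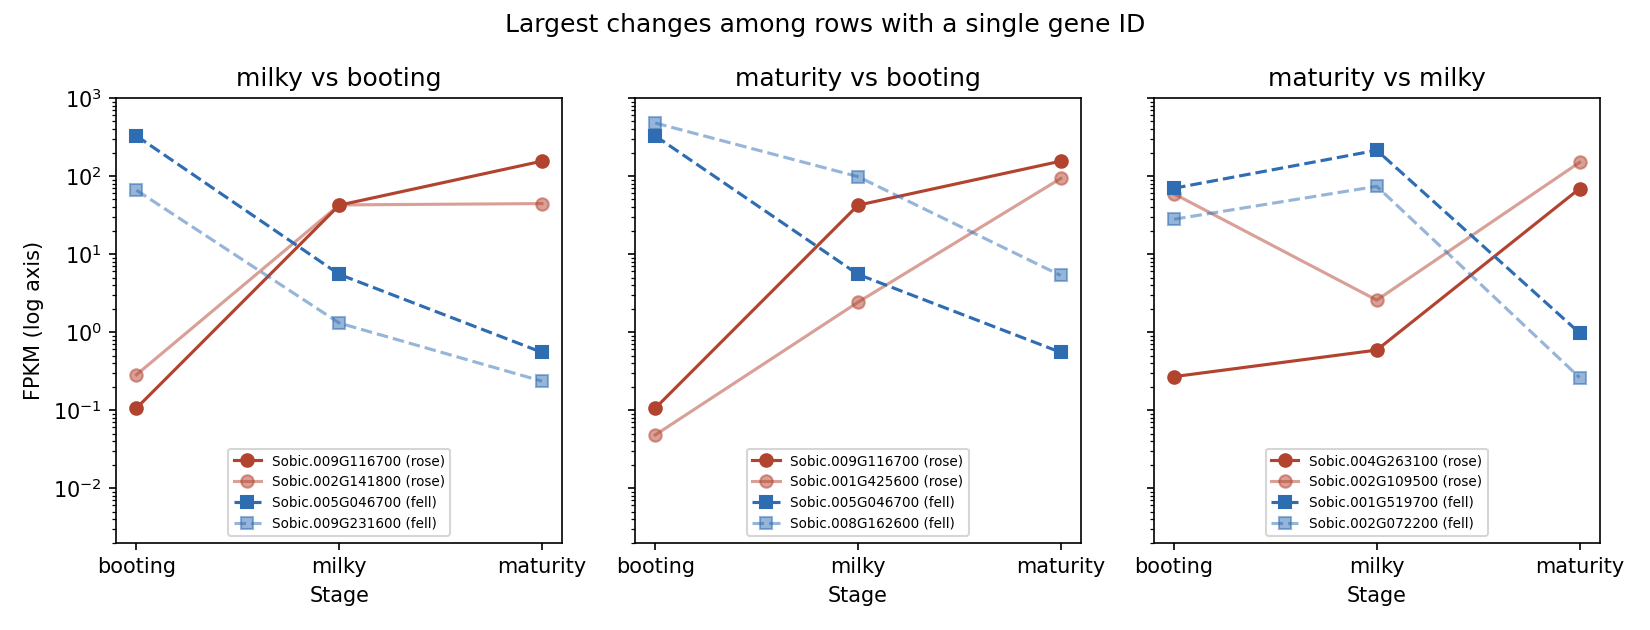
FPKM (log axis) at the 3 stages for the genes named in each comparison, with circles and solid lines for those that rose and squares and dashed lines for those that fell. Each point is the authors' single value for a stage, and Sobic.005G046700 runs from 327 at booting to 0.549 at maturity.

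Taking both steps together, 3154 rows (17.0%) changed in at least 1 of them. A change only in the first step was seen in 1442 rows (583 rose, 859 fell) and only in the second in 1168 rows (768 rose, 400 fell). Rows that rose in both steps numbered 74, against a mean of 35.2 over all orders of the 3 values within each row, and rows that fell in both numbered 35, against 35.2. Rows that rose and then fell numbered 237, against 493, and rows that fell and then rose numbered 198, against 302. Each mean includes the observed order and its reverse, so it is not independent of the counts set beside it. The mean for rows that fell in both steps thus also holds the 74 that rose in both, and no excess or shortfall was tested. A further 493 rows rose and 309 fell from booting to maturity without reaching the threshold in either step.

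Changes were more frequent among unannotated loci than among rows with a single gene ID. From the milky stage to maturity 15.5% of 986 unannotated rows changed, against 8.96% of 16336 single-ID rows, and from booting to maturity 19.0% against 14.2%. Among single-ID rows, short loci changed most often. In the fifth of rows with the shortest loci, 103 to 2442 bp, 13.2% rose and 13.0% fell from booting to maturity, against 6.21% and 3.06% in the fifth with the longest loci. Neither contrast was matched for expression level, with which the share of changed rows also differed. From the milky stage to maturity, 10.4% of rows with a mean under 1 FPKM rose and 4.15% fell. Among rows with a mean of 10 to 100 FPKM the shares were 3.59% and 2.98%.

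The largest rise among rows with merged IDs lay on chromosome 3 from 7023231 to 7058676, a locus singled out after its values were seen. Its 2 rows rose from 0.304 through 16.2 to 1388 FPKM (a log2 difference of 10.06 from booting to maturity) and from 49.1 through 341 to 3077 FPKM (5.94). A separate row at 7078510 to 7079627 went from 0.0485 through 2.26 to 88.5 FPKM (6.42). The row between them, at 7064827 to 7066421, stood at 233, 299 and 153 FPKM. Each merged row covers more than 1 annotated gene, so its value does not belong to 1 gene.

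**Figure D3:**
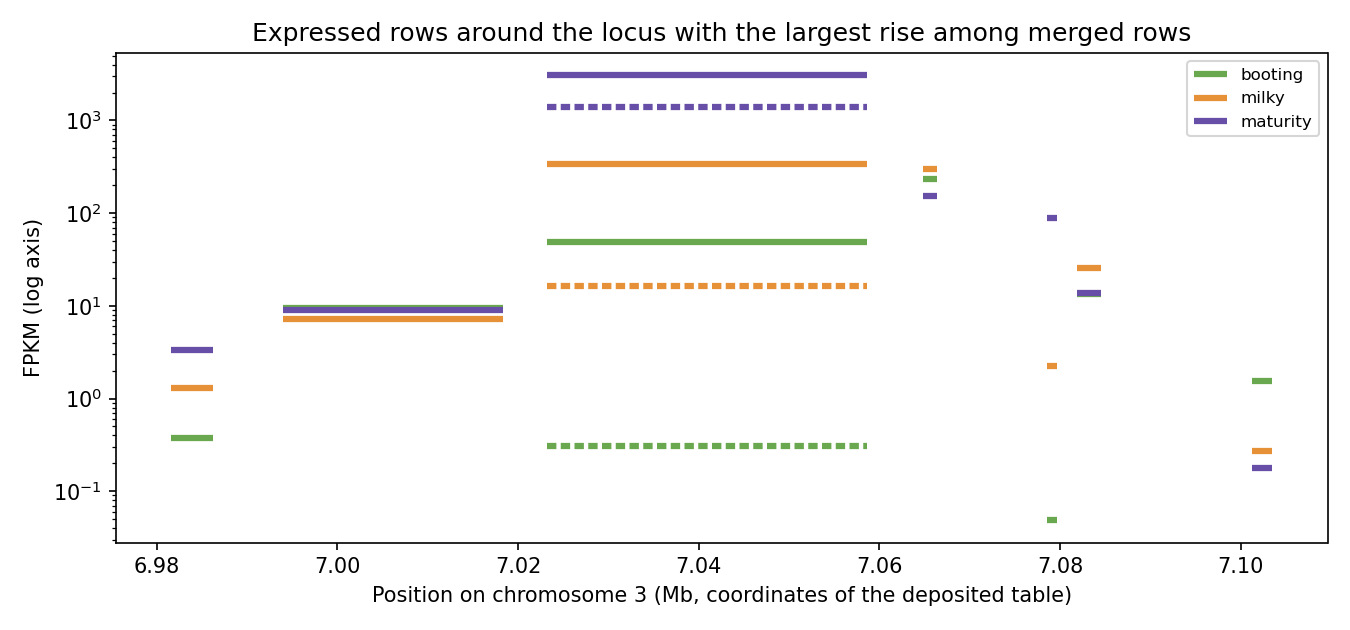
FPKM (log axis) of the expressed rows within 50000 bp of the merged locus on chromosome 3, against position in Mb, with each line spanning a row's locus and colours for the stages. The merged locus holds 2 rows with the same coordinates, the dashed one reaching 1388 FPKM and the solid one 3077 FPKM at maturity, while the row beside it at 7064827 stood at 153 FPKM.

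Across the 18505 expressed rows, log2(FPKM + 1) correlated between milky stage and booting with Pearson's r of 0.941 and Spearman's rho of 0.939. The values were 0.917 and 0.915 for maturity and booting, and 0.940 and 0.939 for maturity and the milky stage. These correlations are across rows, which are not independent replicates.

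A few abundant rows were listed at 0 in another stage, and no fold is given for them. Of 1670 rows that reached 100 FPKM in a stage, 4 were at 0 in another. A row on chromosome 1 from 12370478 to 12374638 was listed at 0 at booting and had 4107 FPKM at the milky stage and 4007 at maturity. At chromosome 10 from 52122843 to 52228422, a row with 1879 FPKM and another with 320 FPKM at the milky stage were listed at 0 at booting and maturity. The fourth, an unannotated row on chromosome 1 from 1169606 to 1171177, was listed at 0 at booting and had 103 FPKM at the milky stage and 1.29 at maturity.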

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

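The restriction to single-ID rows, the omission of rows at 0 and the ratio without a pseudocount were chosen after seeing the data; the other settings were fixed before. The total of changed rows stayed within 1.5 times the main count in every comparison after rescaling by the median of ratios and after quantile normalization. It also did so under those added settings. Leaving out the filter could not change the totals, since a row under 1 FPKM in every stage cannot differ by 1 in log2(FPKM + 1). The main totals were 1986 for milky vs booting, 2645 for maturity vs booting and 1712 for maturity vs milky. In the same order, a pseudocount of 5 gave 847, 1167 and 668, a mean of at least 5 FPKM gave 1265, 1529 and 955, and a log2 difference of at least 2 gave 308, 567 and 341. A pseudocount of 0.1 gave 3182 for milky vs booting, 3853 for maturity vs booting and 2722 for maturity vs milky. Of these, only 3853 stayed within 1.5 times the main count. Rows changed in at least 1 step numbered 584 at a log2 difference of at least 2, against 3154. These moves follow from how much weight low values receive, how many rows enter or how large a change must be. In maturity vs booting, the excess of rises also turned with a pseudocount of 5 (565 rose, 602 fell), and in milky vs booting the excess of falls turned with a pseudocount of 0.1; the cause was not tested. All 12 log2 differences of named genes kept their direction with a pseudocount of 0.1 and after rescaling, which was bound to happen and is no check. A pseudocount cannot change which stage is higher, and the rescaling factors lay between 0.983 and 1.04. With a pseudocount of 0.1, the fold that the log2 difference stands for moved by over 1.5 times for 9 of the 12.

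No paired analysis was possible because each stage has a single value. For the same reason the limma alternatives and those without booting replicate 1 or 2 were not run, and the gene list medians had no members.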

Other observations

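In this part, the tests of recurring low values, of rows at 0 and of pairs split at 10 kb were chosen only after the result was seen, and the test within expression bins was fixed before its result. The longest runs of neighbouring rows that changed together had 5 rows. One fell from booting to maturity on chromosome 3 from 28848740 to 28861779, with a median of 21.9 FPKM at booting, 13.2 at the milky stage and 7.75 at maturity. Another fell from booting to the milky stage on chromosome 1 from 15797996 to 15872166.

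Neighbouring rows changed in the same direction more often than shuffled calls gave in each comparison, 181 pairs against a mean of 101 for milky vs booting, 279 against 178 for maturity vs booting and 167 against 76.8 for maturity vs milky. Clustering of weakly expressed rows does not account for the last, since shuffling within 10 bins of mean expression gave at most 109 pairs against the 167 observed. Overlap or read-through of adjacent transcripts is argued against for pairs over 10 kb apart, of which 78 changed together against at most 54 in 1000 shuffles. For pairs up to 10 kb apart it cannot be told apart from shared regulation, since both would give the excess seen there, 89 pairs against at most 68. Reads shared between similar neighbouring genes were not tested, and no biological explanation was tested.

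In rows with a gene ID as row ID and an unshared locus over 600 bp, FPKM was multiplied by locus length less an offset. The offset was 170 bp at booting, 163 at the milky stage and 169 at maturity. It was fitted to put the most rows on the first value. In the lowest of these rows, the product fell on recurring values. The first and the second were 0.0101 and 0.0153 FPKM kb at booting, 0.0111 and 0.0162 at the milky stage and 0.0112 and 0.0128 at maturity. A candidate explanation, that each stage value averages 2 libraries of different depth, needed the second value and the sum of both to hold at least 3 times the background rows in every stage. The second value did, with 47, 27 and 93 rows at booting, milky stage and maturity over a background of 2, 3 and 4. It was chosen as the fullest window in its range, so it was bound to exceed the other windows there. The fullest of those held 6, 12 and 17 rows. The sum also met the bound at booting (17 rows, background 3, fullest other window 9) and maturity (27, 5 and 13). At the milky stage the sum held 11 rows over a background of 4, a ratio of 2.75, within counting error of the bound by a Poisson limit applied after the shortfall was seen, and the fullest other window also held 11, so the explanation stays open; the labels list 1 library each for the milky stage, numbered 2, and maturity, and do not settle how many libraries entered those values. Fractional weights of reads with several alignments would give the same ratio in every stage, and the ratio of the second value to the first differed by 0.368 between stages.

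For abundant rows listed at 0, a failed estimate of a whole locus could be the source. On chromosome 10 from 52122843 to 52228422, 3 of 3 rows of the locus were at 0 in the same stages. Of these, 2 prompted the test and the other reached only 0.659 FPKM in any stage, so a failed estimate cannot be told apart there from absence of transcript. The row on chromosome 1 from 12370478 is the only row of its locus, 1 of 1, and a failed estimate cannot be told apart there from absence of transcript at booting. It was also the only row at 0 in exactly 1 stage with 10 FPKM or more in both others. Among the remaining rows at 0 in exactly 1 stage, the lower of the other stages reached at most 6.89 FPKM. That sets the row apart but does not decide between a failed estimate and absence of transcript. For the unannotated row from 1169606, 1 of 2 rows of the locus was at 0, and the other had 5126 FPKM at booting, which argues against a failed estimate of the whole locus.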
